A study of Mus musculus with 10 samples.

How the data were processed

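RNA sequencing values were taken from 2 gene tables, 1 for KrasT and 1 for MycT tumours, with 1 column per library. Per the labels, total RNA came from frozen tumour tissue of athymic nude mice, before or after doxycycline, and libraries were made with an Illumina TruSeq RNA kit. The tables hold FPKM (fragments scaled to gene length and to the mapped fragments of the library), as the authors deposited them. Per the submitters' processing notes, cutadapt and TopHat were used with the mm9 build. The program and annotation behind the FPKM values, and whether counting used strand, are not given in the sources used here. No scaling between libraries beyond FPKM is stated. The depth in reads is unknown, and relative depth was estimated only from the steps between values of rarely detected genes.

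Columns were matched to samples by the animal number in their names. One untreated MycT column carries a number that matches no label, so it was used as an untreated MycT replicate without a number. Each table has 23951 rows. In each, 27 rows whose symbols had turned into dates were left out, and no other symbol occurred more than once. No coordinates are given, because the gene table used here is of GRCm38 and the authors' build is mm9. That table served only for gene lengths, with a match for 94.5% of the genes tested in MycT. Of 20 genes that nearly all cells use, 0 were listed at 0 in any library.

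Groups came from the labels: 3 untreated and 3 doxycycline KrasT, 2 untreated and 2 doxycycline MycT. The labels give each tumour its own animal number, and no number pairs samples. Exact permutation could reach p = 0.1 at best with 3 against 3 and 0.333 with 2 against 2, so tests rest on a spread shared across genes. Genes were kept at an FPKM of at least 1 in at least 3 KrasT or 2 MycT libraries. Changes were tested on log2(FPKM + 1) within each table with limma 3.58.1 in R 4.3.3 (eBayes with a trend, two-sided), and genes were called at a Benjamini-Hochberg adjusted p under 0.05. The difference between models was the interaction term of 1 fit over both tables. The 29 gene lists (16 pathways and 13 sets of cell type markers) were tested where at least 5 genes were kept, by camera with a preset correlation of 0.01, and beside it by camera with an estimated correlation and by fry. The shared calls were tested with Fisher's exact test. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

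Tests, lists, alternatives and the rule for named genes were fixed before the data were examined. Per model the rule names the 10 largest rises and 10 largest falls among called genes without overlap between groups and with a mean of at least 5 FPKM in the higher group. Predicted genes, clone names and small RNAs are left out. Where no gene on a side passes, it names the 5 largest of the others. For the difference between models it names up to 5 genes per side. It adds a set of fixed genes, among them Myc, Igf1, Igf1r, Igf2, Mki67, Cdkn1a and Cdkn1b, and per list up to 2 called rises and 2 called falls, or the 2 genes of smallest p. Some genes that the rule names are not reported here.

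The steps were tested on simulated log values with 200 changed genes. Means and spreads were those of the real genes, except that very small spreads were raised to a floor. Changed genes had an untreated level of at least 5 on the log2(FPKM + 1) scale, so the shares below hold for well expressed genes. Noise was drawn for each gene on its own, so shifts of many genes together in a library are left out. For KrasT (12696 genes), 2.99% of genes changed by 1 log2 unit were recovered, 47.8% of those changed by 2 and 81.8% of those changed by 4, with 6 false calls. For MycT (12834 genes) the shares were 0%, 0% and 28.8%, with 1 false call. For the difference (12073 genes) they were 0%, 35.8% and 74.2%, with 11 false calls. A list moved by 1 log2 unit was found by camera in 18 of 20 KrasT and 15 of 20 MycT simulations with independent genes, and with an estimated correlation in 11 and 0.

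Alternatives were a pseudocount of 0.1, no filter on low values, a mean FPKM of at least 5, median-ratio scaling, quantile normalization, robust spread, spread without a trend, library weights, a joint fit of both tables and leaving out each library. A fit without the libraries whose Rn45s was above 10000 FPKM, and the test of lists between models, were added after seeing the data.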

Results

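RNA was sequenced from mouse pancreatic tumours growing in the pancreas of athymic nude mice, which lack a thymus. The tumours came from 2 models, called KrasT and MycT in the labels. Host mice either received no doxycycline or drank doxycycline at 100 ug/ml in 2.5% sucrose for 2 weeks. Doxycycline is the drug used to switch tetracycline-controlled transgenes, and the study asks what tumours look like when their driving oncogene is off. The labels do not say how the transgenes are built. They name no sucrose for untreated mice, and all doxycycline tumours are of these 2 models. Effects of sucrose or of doxycycline itself therefore cannot be told apart from those of switching off the oncogene. There were 3 untreated and 3 doxycycline KrasT tumours, and 2 untreated and 2 doxycycline MycT tumours, 10 libraries in all. Whole tissue was extracted, so each value sums over tumour cells and all other cells in the piece.

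Expression was given as FPKM for 23924 usable gene symbols in each of 2 tables. Read totals are not in the tables. Relative depth, read from the value steps of rarely detected genes, ran from 0.756 to 1.188 of the first untreated library in KrasT and from 0.621 to 1.0 in MycT. Total FPKM was higher in untreated libraries (790759 to 1020439 in KrasT and 1127555 to 1518389 in MycT) than in doxycycline libraries (514668 to 569975 and 546555 to 557828). Ribosomal protein genes took 28.9% to 37.4% of untreated KrasT values and 16.7% to 28.2% after doxycycline. In MycT they took 49.9% and 53.8% of untreated values and 23.7% and 23.8% after doxycycline. KrasT doxycycline replicate 1 and MycT doxycycline replicate 2 had Rn45s, the ribosomal RNA precursor, at 17238 and 20880 FPKM, against at most 2231 in the other libraries.

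The first comparison asks which genes differ between untreated and doxycycline KrasT tumours. After doxycycline the tumours had far more Igf1 and less Myc. Among genes of fixed lists, 11 of 20 mitotic and 7 of 15 glycolytic genes were lower, and 12 of 19 fibroblast and 9 of 12 endothelial genes higher, though none of these lists passed as a whole with an estimated correlation. Igf1, a secreted growth factor, rose from 1.04 ± 0.169 FPKM (SD, n = 3) to 42.84 ± 4.33 FPKM (SD, n = 3). Its log2 change was 4.43 ± 0.24 (SE), with a limma adjusted p of 0.000982. All log2 changes are of FPKM + 1, which understates changes of low genes. Myc fell from 45.4 ± 24.6 to 8.89 ± 3.25 FPKM (log2 change -2.15 ± 0.43 SE, limma adjusted p = 0.0236). The labels do not say whether transgene reads count under mouse symbols, so the values do not check the labels.

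In KrasT, 2121 of 12696 tested genes passed limma's adjusted p of 0.05, 1074 higher and 1047 lower after doxycycline. Under median-ratio scaling 1302 were higher and 492 lower, so the share of higher genes among the calls went from 50.6% to 72.6%. The median log2 change of all genes was -0.10 in the main scaling and 0.14 under median-ratio scaling, a shift of 0.24. Groups did not overlap for 5058 genes, 39.8% of those tested, where chance gives 10%. The count depended on every single library: without untreated replicates 1, 2 and 3 it was 4384, 165 and 103, and without doxycycline replicates 1, 2 and 3 it was 1088, 966 and 103. The Igf1 call held in all 6 of these fits and the Myc call in 2. Myc lost its call without untreated replicates 2 or 3 or doxycycline replicates 2 or 3. Untreated replicate 1 stood apart from its group, with a Pearson r across genes of 0.823 and 0.839 to the others, which had 0.966 between them.

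The largest rises in KrasT included matrix and fibroblast genes. Dpt, which codes for dermatopontin, went from 0.646 ± 0.756 to 130.2 ± 16.5 FPKM (log2 change 6.40 ± 0.36 SE, limma adjusted p = 0.000982). Dcn, the proteoglycan decorin, went from 37.5 ± 27.4 to 1368 ± 309 FPKM (5.35 ± 0.48 SE). Clec3b, Mfap4, Gdf10 and Pi16 had log2 changes of 5.55, 5.39, 5.69 and 5.35. The adipocyte gene Cfd and Car3, a gene of fat and muscle, rose by 5.999 and 5.83 with a large spread. Cfd was 1135, 28.5 and 17.2 FPKM in the 3 doxycycline libraries. Gpnmb rose by 5.64, with 604 FPKM in doxycycline replicate 1 and 22.3 and 38.9 in the other libraries. Sst, the islet hormone somatostatin, rose by 5.48. The calls of Cfd, Car3, Gpnmb and Sst held in 2, 1, 3 and 5 of the 6 fits that left out 1 library.

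The largest falls in KrasT were in genes of varied function. Areg, an EGF receptor ligand, fell from 106.7 ± 68.1 to 0.375 ± 0.139 FPKM (log2 change -6.09 ± 0.48 SE, limma adjusted p = 0.00269). Prkg2, a cGMP-dependent kinase, fell from 143.7 ± 35.4 to 1.255 ± 0.547 FPKM (-6.004 ± 0.30 SE). Hmga2, a chromatin protein of embryonic and tumour cells, fell from 178.4 ± 89.2 to 2.57 ± 0.827 FPKM (-5.57 ± 0.39 SE). Synpr, Prss22, Ptprn and Aldh1a3 had log2 changes of -5.94, -5.55, -5.32 and -5.16. Prm1 had a change of -6.03, and its call held in 1 of the 6 fits that left out 1 library. The calls of Prss22 and Aldh1a3 held in 3 of these fits each. Klra18 (-5.60) has near-identical copies, so its value is uncertain.

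**Figure D1:**
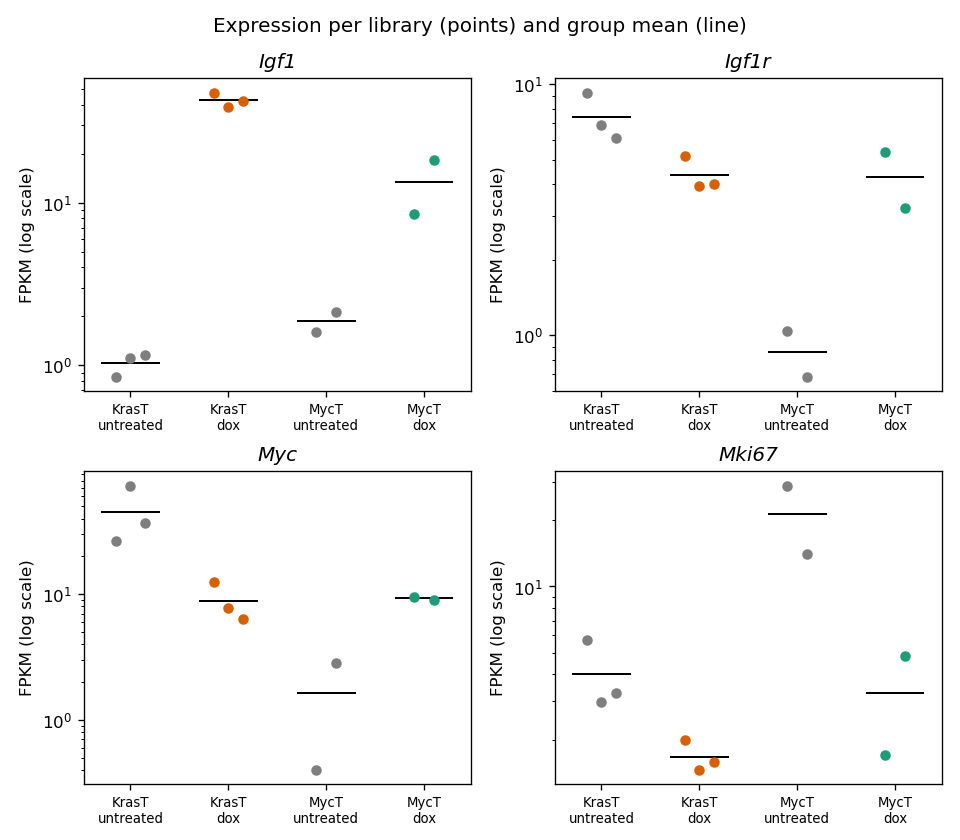
FPKM of Igf1, Igf1r, Myc and Mki67 on log axes, with 1 point per library and a line at each group mean. The 3 KrasT doxycycline libraries have Igf1 between 38.9 and 47.5 FPKM, and the 3 untreated ones between 0.843 and 1.15.

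Gene lists fixed in advance were then compared in KrasT. In the G2/M and mitosis list all 20 tested members had negative changes, with a median of -1.37, and 11 passed the test over all genes (20 adjusted over the list alone). The list did not pass with an estimated correlation (adjusted p = 0.459). Ube2c went from 27.6 ± 5.92 to 4.25 ± 1.02 FPKM and Ccnb1 from 11 ± 3.39 to 1.43 ± 0.842 FPKM. The proliferation gene Mki67 changed by -0.86 ± 0.29 (SE) and did not pass (limma adjusted p = 0.0900). Of 24 DNA replication genes, 2 fell over all genes (1 adjusted over the list alone), among them Rrm2 with -3.14 and Pcna with -0.96. Of 25 MYC-linked genes of ribosome biogenesis and nucleotide synthesis, 9 fell (14 adjusted over the list alone), with Nme1 at -1.63 and Eif5a at -1.45. Of 18 MAPK output and feedback genes, 10 fell (11 adjusted over the list alone), with a median of -1.89. Dusp5, an ERK phosphatase, had a log2 change of -4.22 and Etv4, an ERK-induced transcription factor, one of -3.80. Of the 6 fits that left out 1 library, the call of Etv4 held in 6, Ube2c and Rrm2 in 4, Ccnb1 in 3, Nme1, Eif5a and Dusp5 in 2 and Pcna in 0.

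Glycolysis genes fell in 7 of 15 members (12 adjusted over the list alone), with a median of -1.87. Pgk1 went from 1232 ± 502 to 105.2 ± 34.9 FPKM and the glucose transporter Slc2a1 from 213.1 ± 165.6 to 15.9 ± 3.94 FPKM. Of 24 oxidative phosphorylation genes, 3 fell (3 adjusted over the list alone), with Cox5a at -1.25 and Uqcrfs1 at -1.18. The median of that list was -0.54 in the main scaling but 0.07 under quantile normalization, where its camera call was lost and its direction turned. In the IGF axis list, 4 of 14 genes rose (5 rose and 1 fell adjusted over the list alone), led by Igf1 and by Igfbp6 with 4.38. Igf1r had 7.43 ± 1.64 FPKM untreated and 4.37 ± 0.707 FPKM after doxycycline (limma adjusted p = 0.148). Igf2 had 0.696 ± 0.489 and 3.45 ± 2.71 FPKM (limma adjusted p = 0.0993). Of 15 interferon and antigen presentation genes, 4 rose (4 adjusted over the list alone), with Psmb8 at 2.51 and Ifi44 at 1.94. Of the 6 fits that left out 1 library, the call of Pgk1 held in 5, Igfbp6 in 4, Uqcrfs1 and Ifi44 in 2, and Slc2a1, Cox5a and Psmb8 in 1.

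Cell type markers also differed in KrasT. Fibroblast and matrix genes rose in 12 of 19 members (15 adjusted over the list alone, with 1 lower), with a median of 2.08, and Lum changed by 4.47. Endothelial genes rose in 9 of 12 (10 adjusted over the list alone, with 1 lower), with Pecam1 at 2.53 and Eng at 2.41. Macrophage genes rose in 3 of 16 (8 adjusted over the list alone), with Emr1 at 2.98 and Csf1r at 2.81. Neutrophil genes rose in 3 of 6 (5 adjusted over the list alone), with S100a9 at 2.22 and Csf3r at 2.09. None of the 5 T and NK cell genes passed over all genes, and 5 did adjusted over the list alone, with Gzma at 1.48 and Nkg7 at 1.26. Adipocyte genes rose in 3 of 8 (3 adjusted over the list alone), with Lpl at 4.91. Islet genes rose in 3 of 9 (4 adjusted over the list alone), with Ppy at 4.65. None of 17 acinar genes passed in either count, with a median of 3.44, and Pnlip (5.44 ± 1.95 SE) and Cela2a (4.99 ± 2.02 SE) were led by doxycycline replicate 3. None of 11 skeletal muscle genes passed in either count, with a median of 3.37. Ckm was 630.5 FPKM in doxycycline replicate 2, against 8.79 and 34.1 in the other doxycycline libraries, with Pvalb at 412 against 1.85 and 23.0. Of the 6 fits that left out 1 library, the calls of Lum, Pecam1, Csf3r, Lpl and Ppy held in 3, Eng and Csf1r in 2, Emr1 in 1 and S100a9 in 0.

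By camera with its preset correlation, 17 of the 26 lists with enough genes passed in KrasT. The 6 lower lists were mitosis, DNA replication, MYC-linked, MAPK output, glycolysis and oxidative phosphorylation, with adjusted p from 9.51e-08 (mitosis) to 0.00921 (DNA replication). The 11 higher lists were IGF axis, interferon, acinar, islet, fibroblast, macrophage, neutrophil, T and NK, endothelial, adipocyte and skeletal muscle, with adjusted p from 3.16e-07 (fibroblast) to 0.00701 (adipocyte). None held with an estimated correlation, where the lowest adjusted p = 0.459. Splits of the 6 libraries that mix the groups also gave 3 to 14 calls with the preset correlation, though they still carry part of the doxycycline difference. With the preset correlation, oxidative phosphorylation (adjusted p = 0.7595) and T and NK cells (0.05196) lost their calls under quantile normalization. DNA replication lost its call without untreated replicate 1 (0.2149), and skeletal muscle without doxycycline replicate 2 (0.06108). By fry, which asks whether a list's own genes move one way, 8 lists passed: mitosis, MYC-linked, MAPK output, IGF axis, fibroblast, T and NK, endothelial, and apoptosis (lower, adjusted p = 0.03755), which camera did not call. The apoptosis median turned from -0.16 in the main scaling to 0.08 under median-ratio scaling and 0.06 under quantile normalization, so its direction is not settled. With the preset correlation, autophagy was called as higher under quantile normalization (adjusted p = 0.04205) though lower in the main fit.

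The other lists did not pass camera in KrasT and held a few called genes. JAK-STAT signalling (adjusted p = 0.234) had 2 of 13 higher (3 higher and 1 lower adjusted over the list alone), Il6st with 1.66 and Stat5b with 1.01. Autophagy and lysosome (adjusted p = 0.746) had Gabarapl1 higher by 1.11, 1 of 23 in both counts. Apoptosis regulators (camera adjusted p = 0.673) had 2 of 19 higher and 2 lower (3 and 3 adjusted over the list alone), with Bmf at 2.37, Fas at 1.93 and Pmaip1 at -1.74. Cell cycle inhibitors (adjusted p = 0.557) had 1 of 19 higher and 2 lower in both counts, with Gas1 at 2.41, Cdkn2b at -2.12 and Btg1 at -1.46. Cdkn1a (-2.03 ± 0.72 SE, limma adjusted p = 0.0994) and Cdkn1b (-0.13 ± 0.42 SE, limma adjusted p = 0.858) did not pass. Progenitor markers (adjusted p = 0.329) had 4 of 12 higher and 1 lower (4 and 2 adjusted over the list alone), with Aldh1a1 at 2.86, Dclk1 at 2.71 and Cd44 at -1.76. The unfolded protein list (adjusted p = 0.171) had Hspa5 lower by a log2 change of -1.20, 1 of 12 in both counts. Snai1 was higher by 1.35 in the EMT list (adjusted p = 0.235), 1 of 7 in both counts, and Jun by 1.75 in the immediate early list (adjusted p = 0.666), 1 of 10 in both counts. Ductal epithelium (adjusted p = 0.183) had 2 of 14 lower in both counts, the keratins Krt18 with -3.60 and Krt8 with -3.09. B cell, erythroid and hepatocyte lists had 3, 4 and 2 tested genes, too few for camera, with medians of 2.27, 1.77 and 3.56. Of these, Cd79a at 2.52 (3 of 3 B cell genes adjusted over the list alone), Ttr at 4.85 and Alb at 2.27 passed over all genes. Hba-a2 at 3.08 and Alas2 at 0.999 did not. Of the 6 fits that left out 1 library, the call of Dclk1 held in 6, and Ttr and Alb in 4. Il6st, Gas1, Btg1, Aldh1a1, Cd44 and Jun held in 3, Bmf, Cdkn2b, Hspa5, Krt18 and Cd79a in 2, and Stat5b, Gabarapl1, Fas, Pmaip1, Snai1 and Krt8 in 1.

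**Figure D2:**
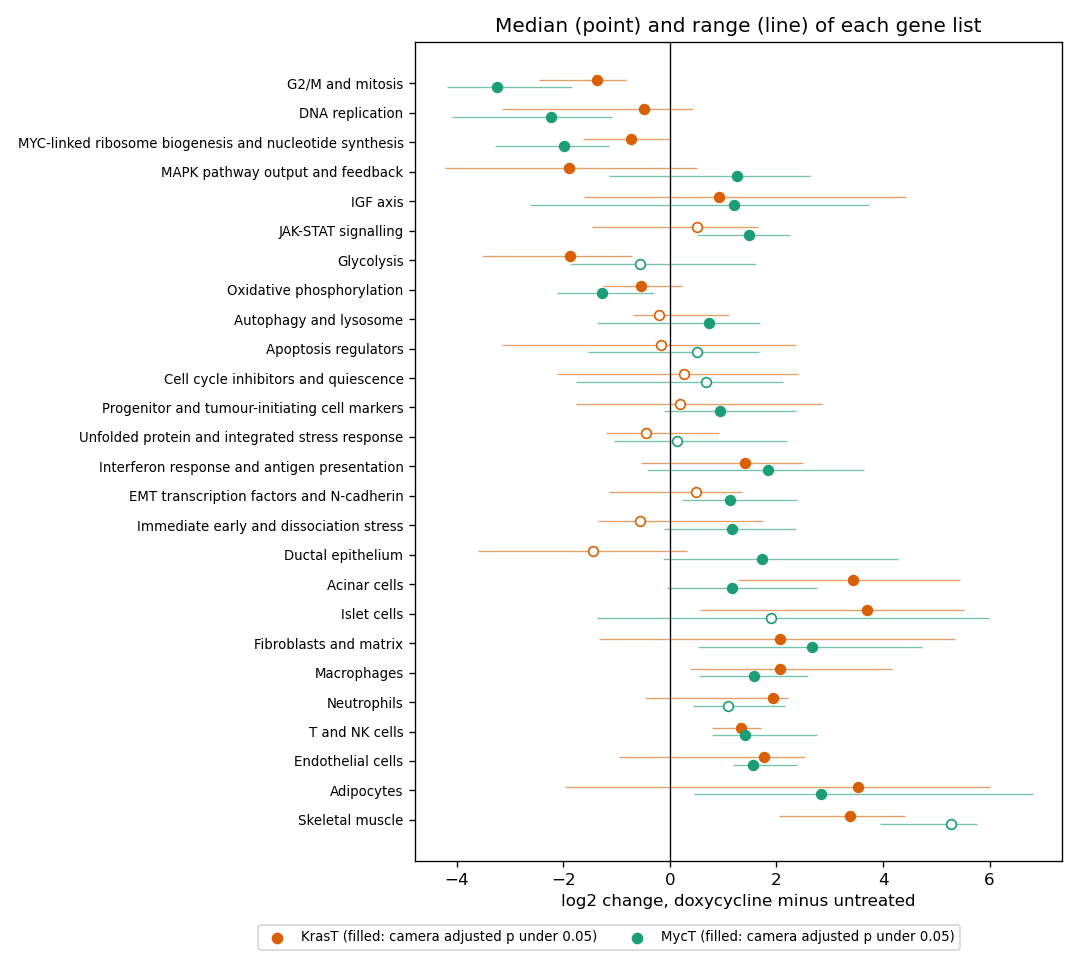
Median log2 change of each tested gene list, doxycycline minus untreated, in KrasT and MycT, with a line from the lowest to the highest member and filled points for a camera adjusted p under 0.05. Mitosis lies at -1.37 in KrasT and -3.24 in MycT, and MAPK output at -1.89 and 1.27.

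The same question was put to MycT tumours, with 2 libraries per group. Values of mitotic, replication and ribosome biogenesis genes were lower after doxycycline and those of fibroblast, endothelial and lymphocyte genes higher. These are shifts of whole lists: no member passed over all genes in the MycT fit, and no list passed with an estimated correlation. In MycT simulations with independent genes that test found a list moved by 1 log2 unit in 0 of 20 runs. Larger shifts, such as the mitosis median of -3.24, and correlated genes were not simulated. How often the test would find these lists is therefore not known. Limma called 5 of 12834 genes, 1 higher and 4 lower, and 4284 had an unadjusted p under 0.05. Car3, a carbonic anhydrase of fat and muscle, rose from 0.247 ± 0.350 to 286.3 ± 7.29 FPKM (SD, n = 2), a log2 change of 7.88 ± 0.36 (SE), with a limma adjusted p of 0.0200. The 4 lower genes fall outside the naming rule and were chosen after their values were seen: Snora15, Snora69, Snora3 and Snora7a, small nucleolar RNAs of 116 to 129 nt in the GRCm38 gene table. All 4 are listed at 0 in both doxycycline libraries. Snora15 was at 286 and 463 FPKM in the untreated libraries, and Snora7a at 138.7 and 199.8. FPKM of such short genes rests on few fragments. No call held in any of the 4 fits that left out 1 library, which gave 0 genes each. Groups did not overlap for 8302 genes, 64.7%, where chance gives 33.3%.

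With all 10 libraries in 1 limma fit, which shares 1 estimate of the spread, 2463 MycT genes passed, 979 higher and 1484 lower. Of the 5 genes above, Car3 was among them, and the 4 small nucleolar RNAs were not tested there. Igf1 was at 1.86 ± 0.383 FPKM untreated and 13.4 ± 6.85 FPKM after doxycycline (SD, n = 2), with a log2 change of 2.25 ± 0.47 (SE). Its limma adjusted p was 0.0698 in the MycT fit and 0.00704 in the joint fit. Myc was at 0.398 and 2.85 FPKM untreated and at 9.54 and 8.98 FPKM after doxycycline (adjusted p = 0.0897, joint limma fit 0.0333). What the MycT transgene contributes under this symbol is not given in the sources used here. Igf1r was at 0.861 ± 0.254 and 4.29 ± 1.54 FPKM (limma adjusted p = 0.0869, joint fit 0.0174). Mki67 was at 21.4 ± 10.4 and 3.28 ± 2.21 FPKM (limma adjusted p = 0.0796, joint fit 0.0117). Igf2 (log2 change 0.03), Cdkn1a (1.24) and Cdkn1b (-1.31) had limma adjusted p of 0.983, 0.177 and 0.210. The largest falls among genes not past the test were Guca2a (-5.11), Akr1c19 (-4.73), Pbk (-4.67), Hmgb2 (-4.34) and Fam183b (-4.18), with limma adjusted p from 0.0521 to 0.0689.

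Among the MycT lists, none had a gene past the test over all genes except by the joint fit, so counts here are adjusted over the list alone. All 22 mitosis genes were lower, with a median of -3.24, Bub1 at -3.20 and Cdk1 at -4.10. Of 27 replication genes 24 were lower, with Prim1 at -3.45 and Rfc4 at -3.52. Of 25 MYC-linked genes 24 were lower, with a median of -1.98, Nop56 at -3.27 and Mrto4 at -3.02. Of 24 oxidative phosphorylation genes 11 were lower, with Cyc1 at -2.11 and Atp5b at -1.99. JAK-STAT signalling had 4 of 13 higher, with Il6st at 2.19 and Stat3 at 1.38. MAPK output had 1 of 14 higher and a median of 1.27, with Ier3 at 2.62 and Spry1 at 1.30. Progenitor markers had 2 of 12 higher, with Dclk1 at 2.36 and Sox9 at 2.10, and Sox9 also stands in the ductal list. Fibroblast genes had 9 of 19 higher, with a median of 2.67, Dcn at 4.73 and Pdgfra at 3.17. Their mean log2(FPKM + 1) was 2.25 in untreated replicate 2 and 4.80 in the unnumbered untreated library. In doxycycline replicates 1 and 2 it was 5.98 and 6.62, so much of the rise rests on untreated replicate 2. Endothelial genes had 8 of 12 higher, with Pecam1 at 2.40 and Tek at 1.45. B cell genes had 5 of 6 higher, with Cd79a at 3.18 and Cd79b at 2.95. T and NK genes had 6 of 10 higher, with Gzma at 2.75 and Ncr1 at 1.43. Adipocyte genes had 8 of 10 higher, with Cfd at 6.80 and Adipoq at 5.005. Acinar genes had 2 of 19 higher, with Cpb1 at 2.31 and Try4 at 2.77. Macrophage genes had 1 of 15 higher, with Mrc1 at 2.39 and Csf1r at 2.59. Their mean level was 4.07 in untreated replicate 2, 5.465 in the unnumbered untreated library, and 5.89 and 6.73 after doxycycline.

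By camera with its preset correlation, 20 of 27 lists passed in MycT. The 4 lower ones were mitosis, DNA replication, MYC-linked and oxidative phosphorylation, with adjusted p from 6.04e-13 to 4.81e-07. The 16 higher ones were MAPK output, IGF axis, JAK-STAT, autophagy, progenitor, interferon, EMT, immediate early, ductal, acinar, fibroblast, macrophage, B cell, T and NK, endothelial and adipocyte, with adjusted p from 6.17e-06 (fibroblast) to 0.0399 (autophagy). None held with an estimated correlation (lowest adjusted p = 0.473), and none passed by fry. The estimated correlation found 0 of 20 lists moved by 1 log2 unit in MycT simulations with independent genes. Larger shifts were not simulated. Its result does not show that the lists were unmoved. With the preset correlation, 7 of the higher calls were lost in some of the 8 other settings. The autophagy call held in 4 of these, progenitor, immediate early, ductal and acinar in 6 each, and IGF axis and interferon in 7 each. Without untreated replicate 2 the calls of autophagy, progenitor, interferon, immediate early and ductal lists were lost, and without doxycycline replicate 1 the same ones except interferon. Acinar was lost without the unnumbered untreated library or doxycycline replicate 2, IGF axis without the former, and autophagy without the latter or with no filter. Interferon genes had a median of 1.85, with Tap1 at 3.65, and 0 of 16 adjusted over the list alone. Their mean log2(FPKM + 1) was 1.75 in untreated replicate 2, 5.015 in the unnumbered untreated library, and 5.64 and 4.87 in doxycycline replicates 1 and 2. Without untreated replicate 2 the list had an adjusted p of 0.4595. IGF axis (median 1.21, Igfbp6 at 3.74), autophagy (0.74, Tfeb at 1.69 and Gabarap at 1.13), EMT (1.12, Twist1 at 2.39 and Snai2 at 2.12), immediate early (1.17, Dusp1 at 2.27 and Egr1 at 2.37) and ductal (1.72) lists had 0 genes past it too. Lists that did not pass camera were glycolysis (median -0.57, with 1 of 15 lower adjusted over the list alone, Pgk1 at -1.88 and Hk1 at 1.62), apoptosis (0.51, Bcl2l1 at 1.67), cell cycle inhibitors (0.69, Rbl1 at -1.76 and Trp53inp1 at 1.59) and unfolded protein (0.13, Xbp1 at 2.19 and Asns at -1.05). Islet (1.90, Ppy at 1.63 and Ins2 at 5.98), neutrophil (1.10, Csf3r at 2.17 and Retnlg at 0.89) and skeletal muscle (5.27) lists did not pass either. Acta1 and Tnnt3 were at 1936 and 1642 FPKM in doxycycline replicate 1, and at 1.96 and 1.53 in replicate 2. Erythroid and hepatocyte lists had 2 and 3 tested genes, with medians of -0.21 and -0.11, Hbb-b1 at -0.64, Hba-a1 at 0.21, Apoa2 at -0.95 and Ttr at 1.58.

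The next comparison asks whether doxycycline acted differently in KrasT and MycT tumours. Each difference is a change within the KrasT table minus a change within the MycT table, because FPKM levels were not scaled across tables. The interaction term passed for 29 of 12073 genes, 5 with a higher change in KrasT and 24 with a lower one. Prkg2 had the smallest adjusted p among the named genes: it went from 143.7 ± 35.4 to 1.255 ± 0.547 FPKM in KrasT and from 1.495 ± 1.40 to 1.54 ± 0.235 FPKM in MycT (difference -6.15 ± 0.57 SE, limma adjusted p = 0.0180). Fam84a, Klra18, Tnfrsf23 and Adamdec1 had differences of -6.34, -6.18, -6.01 and -5.77. Bex1 went from 0.959 ± 0.915 to 10.7 ± 5.63 FPKM in KrasT and from 128.4 ± 64.3 to 13.8 ± 1.53 FPKM in MycT (difference 5.62 ± 0.72 SE, limma adjusted p = 0.0311). Slc43a1, Dtd1 and Myh10 had differences of 3.50, 3.13 and 3.03. The count was 0 without KrasT untreated replicate 2, KrasT doxycycline replicates 2 or 3, MycT untreated replicate 2, or either MycT doxycycline library. It was 3 without KrasT untreated replicate 3, 2 without KrasT doxycycline replicate 1, 1510 without KrasT untreated replicate 1 and 504 without the unnumbered MycT untreated library.

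Of the genes fixed in advance that are reported here, none passed the interaction test. The difference was -4.29 ± 0.75 (SE) for Myc, 2.17 ± 0.46 for Igf1, -2.13 ± 0.43 for Igf1r and 1.55 ± 0.61 for Mki67. Their limma adjusted p were 0.0527, 0.0704, 0.0689 and 0.206. Igf2 (1.24), Cdkn1a (-3.27) and Cdkn1b (1.19) had limma adjusted p of 0.461, 0.148 and 0.426.

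The calls of the 2 models were then set side by side over 12073 shared genes. Car3 was higher in both, the 1 gene shared by 968 KrasT and 1 MycT calls, where 0.0802 is the overlap of independent lists (Fisher's exact test, two-sided, p = 0.0802). With 1 MycT call that p is the smallest the test can give, so it could not have passed. No lower gene was shared, since 0 of the MycT calls among shared genes were lower. At an unadjusted p under 0.01 in both, 205 genes were higher in both, where 45.6 is the overlap of independent lists, and 253 were lower in both, against 85.3. Another 17 genes went opposite ways. In the joint fit, which shares 1 estimate of the spread, 417 genes were higher in both, against 77.7 expected of independent lists, 455 were lower in both, against 134.8, and 41 went opposite ways. Log2 changes had a Pearson r of 0.467 and a Spearman rho of 0.431 across genes, which are not independent replicates, and 65.5% had the same sign.

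**Figure D3:**
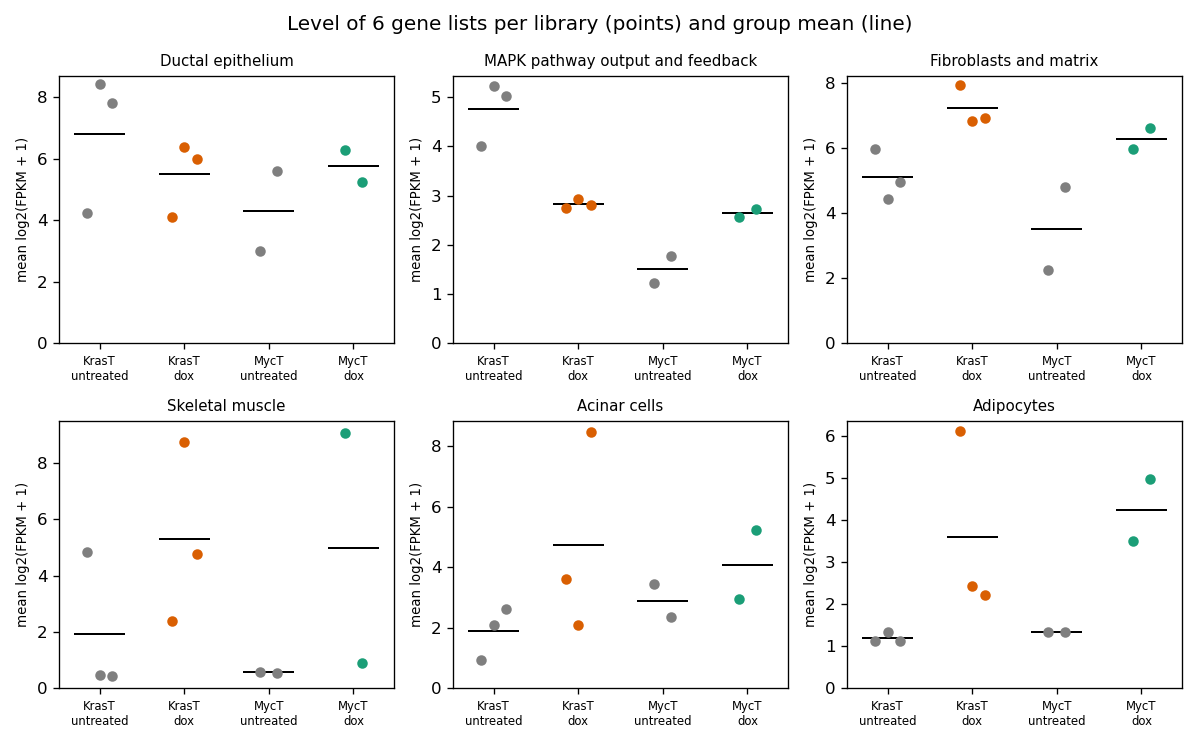
Mean log2(FPKM + 1) over the members of 6 gene lists, with 1 point per library and a line at each group mean. Skeletal muscle reaches 8.74 and 9.06 in 1 doxycycline library of each model, and MAPK output lies between 2.76 and 2.93 in the 3 KrasT doxycycline libraries and between 3.999 and 5.23 in the untreated ones.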

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

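The tests of explanations in this part, and the test of lists between models, were chosen after the results had been seen. The doxycycline response differed between the models, by limma's interaction term, for 29 genes. Among them the difference of log2 changes, KrasT minus MycT, was 5.62 for Bex1, 3.50 for Slc43a1, 3.13 for Dtd1 and 3.03 for Myh10. It was -6.34 for Fam84a, -6.18 for Klra18, -6.15 for Prkg2, -6.01 for Tnfrsf23 and -5.77 for Adamdec1. These genes with a negative difference had untreated MycT means of at most 3.29 FPKM, which left little room for a fall there. On the positive side, Bex1, Slc43a1 and Myh10 had untreated KrasT means of 0.959, 0.333 and 0.685 FPKM, which left little room for a fall in KrasT. Dtd1 had 7.925 FPKM.

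By camera on the interaction term with its preset correlation, 11 of 26 lists differed between models. The median difference, KrasT minus MycT, was 1.79 for mitosis, 1.85 for DNA replication, 1.30 for MYC-linked genes and 0.69 for oxidative phosphorylation. It was -2.81 for MAPK output, -1.26 for JAK-STAT, -1.49 for glycolysis, -0.48 for autophagy, -0.93 for the unfolded protein list, -2.06 for immediate early genes and -3.35 for ductal epithelium. None passed with an estimated correlation (lowest adjusted p = 0.347). By fry 5 lists passed: DNA replication, MYC-linked, MAPK output and JAK-STAT, and apoptosis (lower in KrasT, adjusted p = 0.01207), which camera did not call. The other 7 camera calls did not pass by fry. In the 15 other settings the calls of the autophagy, unfolded protein and immediate early lists held in 11, 12 and 11, and the other 8 lists kept theirs in all. Mean log2(FPKM + 1) of mitosis genes was 2.53 to 3.34 in untreated KrasT and 4.73 and 5.41 in untreated MycT. After doxycycline it was 1.04 to 1.62 in KrasT and 1.44 and 2.58 in MycT. KrasT may thus have had less room for a fall, though levels were not scaled across tables.

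Igf1 was 4.43 log2 units higher after doxycycline in KrasT and 2.25 in MycT, where it passed only in the joint fit. The tables argue against scaling as the whole cause in KrasT, since the lowest rise under the other scalings was 4.37 ± 0.24 (SE). They also argue against RNA from skeletal muscle, acinar cells or adipocytes: over the 3 KrasT doxycycline libraries Igf1 had a log2 range of 0.28, and the median ranges of those markers exceeded it by 6.24, 7.68 and 4.33. Stromal and immune RNA stays open. In MycT, Igf1 lay 0.159 SD above the median of 46 fibroblast, macrophage and endothelial markers, so a larger share of such RNA may account for it there. In KrasT it lay 2.02 SD above the median of 47, beyond a bound of 2 SD by less than its SE of 0.199 SD, and 2 markers rose at least as much. The requirement to exceed the bound by 2 SE was added after that value was seen, so the KrasT rise cannot be told apart from stromal RNA.

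MAPK output genes had a median change of -1.89 in KrasT and 1.27 in MycT. Under median-ratio scaling and quantile normalization the medians were -1.63 and -1.60 in KrasT and 1.44 and 1.07 in MycT, which argues against scaling as the whole cause. The highest camera adjusted p of the difference under these scalings was 4.65e-11, with a preset correlation. Camera compares a list with all other genes, so a shift shared by all genes largely cancels and that p says little on scaling. With an estimated correlation the difference of this list did not pass in the main scaling (adjusted p = 0.347). A change in the share of epithelial RNA stays open and may contribute. The ductal markers moved apart by -3.35 ± 0.52 (SE of the median over genes), at least as much as the -2.81 ± 0.53 of the MAPK list. Both SE treat the genes of a list as independent, though they share libraries, so they do not measure the spread across tumours. The ductal difference did not pass by fry (adjusted p = 0.312). In some libraries MAPK output did not follow the ductal level. KrasT untreated replicate 1 had a mean ductal level of 4.23, against 4.12, 6.40 and 6.01 in the doxycycline libraries. Its MAPK output level was 3.999, against 2.76, 2.93 and 2.81. The unnumbered MycT untreated library had a ductal level of 5.60, against 6.30 and 5.25 after doxycycline. Its MAPK output level was 1.78, against 2.56 and 2.74. Each comparison rests on a single untreated library, so it does not decide the question. A difference between the oncogenes of the models is named by the design and was not tested apart from a change in epithelial RNA.

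Small nucleolar RNAs had a median log2 change of -3.89 ± 0.81 (SE of the median) in MycT, with 18 of 19 lower, and of 1.01 over 9 in KrasT. The SE here are over genes that share libraries, not over tumours. A loss of short genes from the doxycycline libraries could contribute. The other 9 genes of under 200 nt had a median of -1.42 ± 1.53, too uncertain to decide, so this cannot be told apart from a change in these RNAs. No biological explanation was tested.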

How the results depend on the processing

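The joint fit without the libraries of high Rn45s was chosen after seeing the data. The 2121 KrasT genes became 1340 at a mean FPKM of at least 5, where fewer genes were tested, 1078 under quantile normalization, 5935 with library weights and 519 in the joint fit without the libraries of high Rn45s, where the joint fit of all libraries gave 2055. Leaving out 1 library gave 103 to 4384. Of the main calls, 931 remained under quantile normalization and 1566 under median-ratio scaling. The 5 MycT genes became 0 with no filter, 10 at a mean of at least 5, 10 with library weights, 2463 in the joint fit and 253 in the joint fit without the libraries of high Rn45s. Leaving out 1 library gave 0 in each fit, where the lone library is assumed to vary like the other group. The 29 genes that differed between models became 18 with a pseudocount of 0.1, 88 with no filter, 3 at a mean of at least 5, 1475 with library weights and 0 without the libraries of high Rn45s. Leaving out 1 library gave 0 to 1510. Camera with an estimated correlation found 11 of 20 moved lists in KrasT simulations and 0 of 20 in MycT ones. With it, 0 lists passed in KrasT, in MycT and between models. Otherwise the counts of lists were 16 to 20 in KrasT, against 17, 15 to 22 in MycT, against 20, and 8 to 16 between models, against 11, though single lists lost or gained calls. Lists that gained one in KrasT were ductal in 2 of 10 settings, EMT, unfolded protein and immediate early in 1 each, and autophagy in 1, against its main direction. In MycT, islet and glycolysis gained one in 3 of 8, and neutrophil and skeletal muscle in 2. Between models, islet gained one in 7 of 15, interferon in 4, acinar in 3, adipocyte and skeletal muscle in 2, and apoptosis, fibroblast and T and NK in 1. The single shared gene became 458 at an unadjusted p under 0.01, 0 with a pseudocount of 0.1 and 872 in the joint fit, an alternative for this overlap that was chosen after seeing the data. Except where the alternative tests fewer genes or libraries, the cause was not tested.

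The 6 KrasT libraries can be split 3 against 3 in 10 ways, too few for a share under 0.05. The real split gave 2121 genes and the highest other 0, so 1 of the 10 splits reached the real count. It gave 17 lists and the highest other 14, again 1 of 10. The other splits, which mix the groups, gave 3 to 14 lists but 0 genes. Each of these splits still had unequal numbers of doxycycline libraries on its sides, so its list calls may carry part of the doxycycline difference. Mixing the groups also adds that difference to the spread, which works against gene calls. A camera call with the preset correlation can thus arise in a mixed split. These splits cannot say whether such a call marks the doxycycline grouping. No named gene changed direction past the test. Of 1277 values of 81 KrasT genes, 985 kept their side of the threshold and direction and 266 no longer passed. Of 960 values of 70 MycT genes, 889 kept theirs and 56 newly passed. Of 166 values of 9 genes that differed between models, 89 no longer passed. Igf1 in KrasT stayed between 4.34 and 5.25 and passed in all 16 alternatives. In MycT, changes of 2 log2 units were recovered in 0% of simulated genes, so genes that missed the test there are not shown to be unchanged.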

Other observations

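Single libraries carried high levels of genes from other tissues. Prss2 and Cela2a, acinar enzymes, were at 1746 and 3541 FPKM in KrasT doxycycline replicate 3, and at most at 24.4 and 46.3 FPKM in the other KrasT libraries. Ins2, an insulin gene, was at 5559 FPKM in KrasT doxycycline replicate 1, 1824 in replicate 3 and 557 in MycT doxycycline replicate 2. In KrasT doxycycline replicate 2 it was at 4.58 FPKM, below the 47.3 of KrasT untreated replicate 2. The muscle actin Acta1 was at 1544 FPKM in KrasT doxycycline replicate 2 and 1936 in MycT doxycycline replicate 1, and at 144.4 in KrasT untreated replicate 1. Adipoq was at 128.8 FPKM in KrasT doxycycline replicate 1 and 65.9 in MycT doxycycline replicate 2, the libraries in which Rn45s and Lars2 were also high (Lars2 at 11501 and 11508).

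Untreated tumours of 1 model also differed in epithelial and mesenchymal genes. KrasT untreated replicate 1 had Krt7 at 7.1, Epcam at 7.22 and Cdh1 at 4.67 FPKM, against 3348, 374.7 and 370.1 in replicate 2 and 1258, 530.2 and 291.0 in replicate 3. Its Vim and Fn1 were at 2324 and 802 FPKM, against 1474 and 146.6 in replicate 2 and 1202 and 108.1 in replicate 3. Its mean ductal level, 4.23 on the log2(FPKM + 1) scale, was near the 4.12 of KrasT doxycycline replicate 1 and below the 6.40 and 6.01 of replicates 2 and 3. Its MAPK output level, 3.999, was above the 2.76, 2.93 and 2.81 of these 3 libraries. MycT untreated replicate 2 had Col1a1 at 4.59, Vim at 32.4 and Fn1 at 3.44 FPKM, against 55.3, 102 and 64.9 in the unnumbered untreated library. Its epithelial genes were lower too, with Krt7 at 6.24, Epcam at 68.3 and Cdh1 at 12.8 FPKM, against 104.6, 392.1 and 116.4.

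Of the 14 tested MAPK output genes, a list fixed in advance, 2 differed between models, Etv4 and Dusp6, against 29 of all 12073 tested genes. These and Rras, which is in no fixed list, were picked from the 29 genes after their values were seen, so naming them is no test of enrichment. Etv4 (-4.94), Dusp6 (-5.02) and Rras (-3.13) all had a lower change in KrasT than in MycT by limma's interaction term (adjusted p of 0.0311, 0.0490 and 0.0349). Dusp6 was at 108.9 to 201.4 FPKM in untreated KrasT, 17.7 to 30.5 after doxycycline, 1.27 and 8.36 in untreated MycT, and 21.4 and 23.7 after doxycycline. FPKM levels were not scaled across the tables.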
